A study of Odontobutis potamophilus with 2 samples.

How the data were processed

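Libraries of 10x Genomics 3' single-cell RNA were made from head kidney of Odontobutis potamophilus, 1 from a control and 1 after infection with Aeromonas veronii, per the labels. The labels' protocols describe enzymatic dissociation and freezing of the cell suspension, but they speak of a tumor, which differs from the tissue label, so whether these steps were those used on the head kidney is uncertain. The labels do not give the number of fish per library, the dose of bacteria or the time after infection.

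The deposited matrices hold whole-number UMI counts per barcode and feature with no normalization, per the file headers. The submitters' processing notes name Cell Ranger 6.1.2 and Seurat 4.1.3, whereas the file headers name Cell Ranger 4; which version made the deposited counts is not settled by these sources. The reference to which reads were mapped is not given in the sources used here. The matrices list 3584613 barcodes in the control and 3643266 in the infected library, of which 2456471 and 2662940 have a UMI, so they hold all barcodes and not only cells. All 31845 features carry the same identifier in the name column, and no table of gene names was at hand. The 18 cell type marker lists and 19 gene lists fixed before the data were examined could therefore not be matched to features, no cluster was named by type, and no list was tested. Mitochondrial features could not be recognised, so no filter on mitochondrial UMIs was applied. The rule for named features was to give, if features carry no names, at most 2 identifiers higher and 2 lower over all cells, those with the largest fold by the interval bound nearest to equality.

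Cells were called with a rebuilt form of the Cell Ranger 6 rule. Barcodes were cells if they had at least the 99th percentile of the UMI counts of the top 3000 barcodes divided by 10, which gave 1141 UMIs (4739 barcodes) in the control and 914 UMIs (6425 barcodes) in the infected library. Barcodes of at least 500 UMIs below that were tested against the profile of barcodes ranked 45001 to 90000 with 10000 Monte Carlo multinomial draws at a false discovery rate of 0.01. This added 1463 of 1507 control barcodes and 740 of 776 infected barcodes. Barcodes with under 200 features were left out. Doublets were predicted per library with Scrublet in scanpy. Its automatic score threshold was 0.201 in the control library (268 doublets) and 0.589 in the infected library, where it marked 0 doublets and so did not work. The control threshold was then used for both, a choice made after the data were seen, and removed 268 control cells (4.34%) and 212 infected cells (2.96%). The cells kept held 63.3% and 65.4% of all UMIs.

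Cells of both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable features were scaled over all cells and limited to 10, and 30 principal components, 15 neighbours and Leiden resolution 1.0 were used. A cluster was called single-library when at least 95% of its cells came from 1 library. Clusters with at least 50 cells in each library were compared. Their sizes were compared only if fewer than 5 of their 10 leading features passed the size rule within the cluster.

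UMIs were summed per library over all cells and per cluster, and CPM was taken from the total of those cells. A feature passed the size rule with a ratio of at least 2-fold, a conditional exact binomial 95% interval that excludes equality, and at least 50 UMIs in the library with the higher CPM. A count of 0 was replaced by a bound of 3 UMIs. No p-value was computed between libraries. Free RNA was estimated from barcodes of 20 to 100 UMIs, with medians of 36 UMIs in the control and 39 UMIs in the infected library, which is 1.43% and 1.58% of the median cell. Shares of cells with a UMI were computed after thinning each cell to 500 UMIs, and no cell analysed had fewer.

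The size rule was tested on simulated counts for the all-cell comparison, with 100 features changed 2-fold and 100 changed 4-fold. Of these, 198 had enough UMIs to be tested, among 15188 features tested in all, and the others counted as missed. It recovered 47.0% of the 2-fold and 98.0% of the 4-fold changes, and 3 of 14990 unchanged features passed. Intervals held the true ratio for 95.5% of the features. Apart from the changed features, both libraries were drawn as Poisson counts from 1 shared profile, the model behind the intervals. Coverage near 95% and few unchanged features past the rule followed from that choice. Variation between cells was not simulated, so these values are not error rates for the real libraries. The test of barcodes against the empty profile called 0.67% of 300 simulated empty droplets and 77.33% of 300 simulated cells. The simulated empty droplets were drawn from the tested profile itself, so their low rate followed from that choice. The simulated cells were drawn from deep control barcodes only. Of the real control barcodes tested, 1463 of 1507 passed, a higher share than that of the simulated cells, and the reason was not tested.

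Alternatives fixed before the data were examined covered the choice of barcodes, doublets, clustering resolution, scaling within each library, scaling of UMI totals, the UMI minimum, free RNA, the size of the fold and thinning. Alternatives added after the data were seen were each library's automatic doublet threshold, barcodes tested from 200 UMIs, clustering without the features past the size rule, and clustering of thinned cells. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.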

Results

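Single-cell RNA sequencing was carried out on the head kidney of the dark sleeper (Odontobutis potamophilus), a freshwater fish. The head kidney is the main blood-forming and immune organ of bony fishes. The series holds 1 control library and 1 library made after infection with Aeromonas veronii, a bacterium of fresh water that causes disease in fish. The series title gives the immune response of these cells to the infection as the subject. The control matrix held 25895121 unique molecular identifiers (UMIs) and the infected matrix 28810350. After cell calling and doublet removal 5909 control cells and 6949 infected cells were analysed, with medians of 2524 and 2475 UMIs and of 1279 and 1195 detected features per cell. With 1 library per condition no test between conditions was made, the differences have no replicate check, and they compare these libraries, not the conditions. The labels do not state how many fish gave each library. All intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for UMI sums, conditional binomial for ratios) and cover counting error only. Those for UMI sums and their ratios count UMIs of the same cell as independent, so variation between cells is left out. Where a count was 0, the upper limit given is that of 3 counts.

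**Figure D1:**
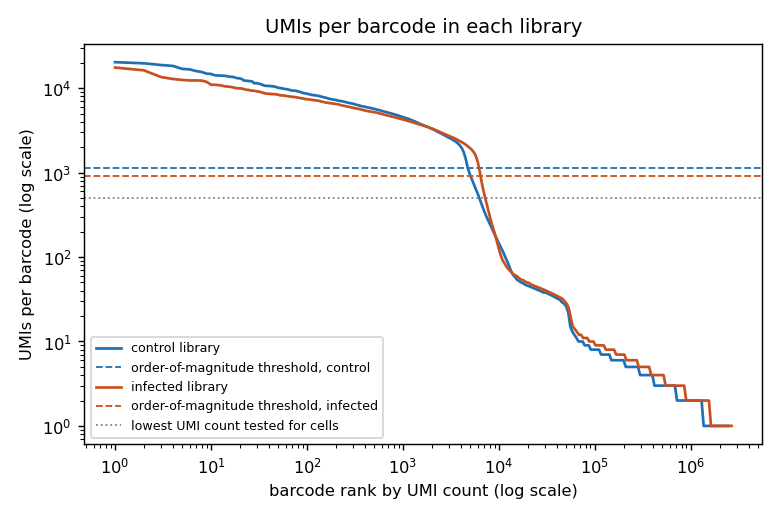
UMIs per barcode against barcode rank, both on log scales, with 1 line per library; dashed lines mark the order-of-magnitude threshold for cells in each library and the dotted line marks 500 UMIs, the lowest count tested for cells. The threshold was 1141 UMIs in the control library and 914 UMIs in the infected library, and the control library had more barcodes of 100 to under 500 UMIs, 5465 against 3431.

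The feature lists hold 31845 features and do not pair their identifiers with gene names. The features below are therefore named by identifier, clusters are named by number, and no cell type is assigned to any cluster. Whether several identifiers belong to the same gene is not given in the sources used here. UMIs of near-identical sequences could have been split between identifiers or dropped, so the level of a single identifier is uncertain as the level of a gene.

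The first comparison asked which groups of cells each library contained. Most cells of each library lay in clusters that the other library barely entered. Of the 31 clusters found in both libraries together, 8 held at least 95% control cells, 9 held at least 95% infected cells and 14 were mixed. The 8 control clusters held 61.5% of the control cells (60.3 to 62.8%), and the 9 infected clusters held 73.4% of the infected cells (72.3 to 74.4%). Cluster 1 held 25.4% of the control cells (24.3 to 26.5%) and 0.101% of the infected cells (0.0405 to 0.207%). Cluster 0 held 31.2% of the infected cells (30.1 to 32.3%) and 0.558% of the control cells (0.385 to 0.783%). Clusters 3 and 5 held 14.1% and 12.7% of the control cells and 0 of 6949 infected cells, which allows a share of up to 0.0432%. On the infected side, clusters 2 and 6 held 12.4% and 9.73% of the cells, against 0.169% and 0.0169% of the control cells. Cluster 7 held 8.16% of the infected cells (7.53 to 8.83%) and 0 of 5909 control cells, which allows a share of up to 0.0508%.

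**Figure D2:**
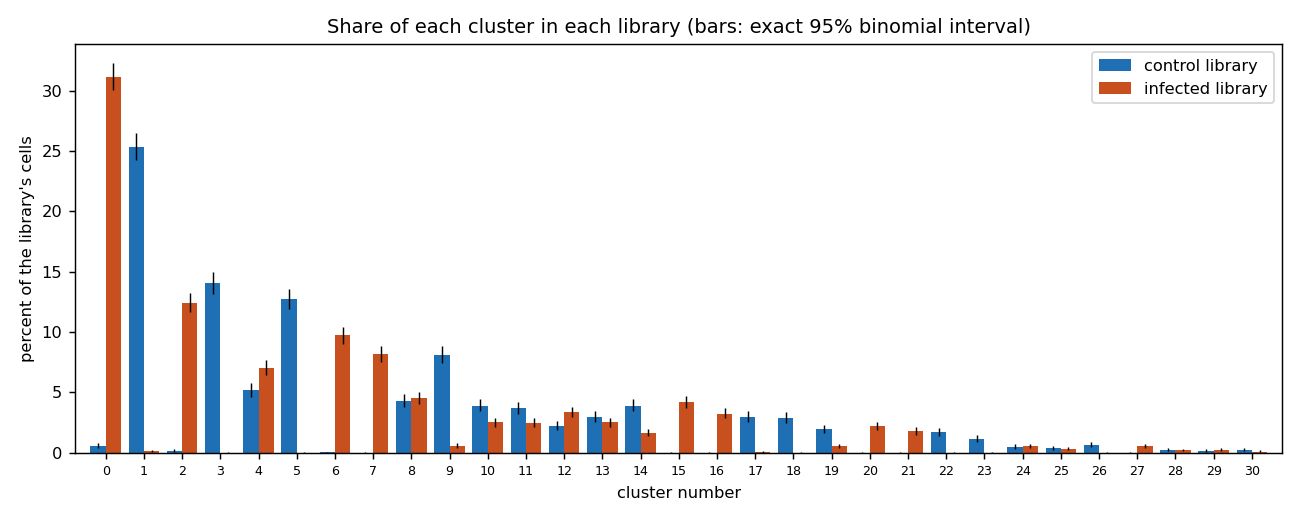
Percent of each library's cells in each of the 31 clusters, with control and infected bars side by side and error bars giving the exact 95% binomial interval. Clusters 0, 2, 6 and 7 are nearly empty of control cells, and clusters 1, 3 and 5 are nearly empty of infected cells.

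The separation was also seen around single cells. Among the nearest neighbours of control cells 6.37% were infected cells, against 54.0% under random mixing. Among those of infected cells 4.03% were control cells, against 46.0% under random mixing. Expression profiles were summed only for clusters with at least 50 cells in a library, so only these could be matched. By summed expression profile, control cluster 1 and infected cluster 0 were each other's closest match, with a Spearman rho of 0.785 across 2000 variable features. This rho is across features, which are not independent replicates. Control clusters 3 and 5 also matched infected cluster 0 best, with rho 0.747 and 0.733. A cluster made almost wholly of cells from 1 library may stand for that library and not for a cell type. A further clustering left out the features that differed between the libraries over all cells. The shares in single-library clusters were then 33.8% of the control cells and 61.1% of the infected cells. Those features were picked from the same cells because they differed, which by itself favours lower shares. With barcodes tested from 200 UMIs the shares were 65.0% and 43.2%.

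Mixed clusters with at least 50 cells in each library allowed a comparison of shares. There were 7 of these, and in clusters 4 and 8 at least 5 of the 10 leading features themselves differed between the libraries, so the sizes of those clusters were not compared. This check depends on depth, so shallow clusters could clear it more easily. Clusters 4 and 8 had 2864 and 3116 features tested, against 394 in cluster 14 and 827 in cluster 11. Cluster 14 took 3.91% of the control cells (3.43 to 4.44%) and 1.65% of the infected cells (1.37 to 1.98%), a share 2.36-fold lower in the infected library. By profile the control cells of cluster 14 matched infected cluster 4 better (rho 0.765) than infected cluster 14 (rho 0.739), so the cells compared may not be the same population. Infected cluster 14 had 87513 UMIs against 730458 in infected cluster 4, and rho was not adjusted for depth. Cluster 11 was also smaller in the infected library, at 3.67% (3.21 to 4.18%) of the control and 2.45% (2.10 to 2.84%) of the infected cells, a log2 ratio of -0.59 (-0.88 to -0.29). Cluster 12 was larger in the infected library, at 2.23% (1.87 to 2.64%) of the control and 3.34% (2.93 to 3.79%) of the infected cells, a log2 ratio of 0.58 (0.27 to 0.90). Infected cluster 12 was also the best profile match of control cluster 9 (rho 0.761), but the infected cells of cluster 9 were too few to be a candidate. Cluster 10 took 3.91% of the control and 2.50% of the infected cells, a log2 ratio of -0.64 (-0.93 to -0.35). The order in cluster 10 depended on which barcodes were taken as cells, since the log2 ratio was 0.10 with barcodes tested from 200 UMIs. The control cells of cluster 13 matched infected cluster 0 (rho 0.678) better than infected cluster 13 (rho 0.649). Infected cluster 0 was also deeper, with 6183374 UMIs against 659397. The shares of cluster 13, 3.00% and 2.52%, were not distinguishable at this depth, with a log2 ratio of -0.25 (-0.56 to 0.06).

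Clusters 9, 17 and 22 were nearly absent from the infected library. Control clusters 1, 3, 5, 18, 23 and 26 were nearly or wholly absent from it as well. Near absence was therefore not particular to clusters 9, 17 and 22. Cluster 9 held 479 control cells, or 8.11% of them (7.42 to 8.83%), and 40 infected cells, or 0.576% (0.412 to 0.783%). Cluster 17 held 177 control cells and 2 infected cells, and a single feature took 33.4% of its UMIs. Cluster 22 held 100 control cells and 0 of 6949 infected cells, which allows a share of up to 0.0432%. By profile, control clusters 9 and 17 matched infected cluster 12 best (rho 0.761 and 0.460) and control cluster 22 matched infected cluster 4 best (rho 0.748). The infected cells of clusters 9, 17 and 22 were too few for a profile and were not among the candidates. Taken as a set, the log2 ratio of their shares was -4.40 (-4.89 to -3.95). Cells of these clusters were shallow, with control medians of 911, 711 and 908.5 UMIs against 2524 over the whole control library, so the UMI minimum for a cell bears on their shares. With barcodes tested from 200 UMIs the log2 ratio was -5.07. With cells assigned by control cluster profiles, 168 infected and 771 control cells fell in these clusters and the log2 ratio was -2.43 (-2.68 to -2.19). The infected cells were too few to see whether the leading features of these clusters differed between the libraries.

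The second comparison asked which features differed in UMIs summed over all cells. Many features were lower in the infected library and fewer were higher. Of 15752 features with at least 50 UMIs in the library where they were higher, 879 were at least 2-fold higher in the infected library and 1563 at least 2-fold lower, with ratio intervals that exclude equality. These counts describe the summed UMIs of these libraries and are not counts of features changed by infection. The median log2 ratio was -0.12. Measured relative to that median, 1022 features were higher and 1298 lower. At a minimum of 200 UMIs the counts were 503 higher and 696 lower, and at 4-fold they were 319 and 434.

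**Figure D3:**
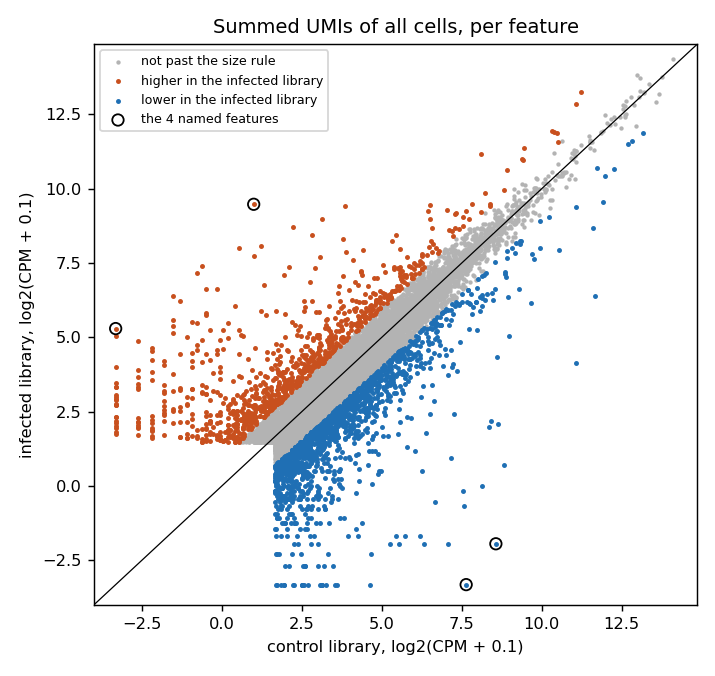
Summed UMIs of all cells per feature, as log2(CPM + 0.1), in the control library (horizontal axis) and the infected library (vertical axis), for features with at least 50 UMIs in either library; CPM is UMIs per 1e6 UMIs of the library's cells. Orange points are the 879 features higher in the infected library, blue points the 1563 lower, and open circles the 4 named features, which lie far from the diagonal.

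Isoform0027597 was the feature highest in the infected library by the bound of its ratio nearest to equality. It had 13379 UMIs in the infected cells (710 CPM) and 31 in the control cells (1.89 CPM), a 376-fold difference (264 to 553). Most of its infected UMIs, 60.2%, came from cluster 6, where it reached 3964 CPM (3877 to 4051), and 18.6% came from cluster 20, where it reached 3560 CPM (3422 to 3703). The difference was also present inside some mixed clusters. In cluster 12 it stood at 1728 CPM (1616 to 1845) in infected cells and at 0 UMIs in control cells, which allows up to 9.58 CPM. In cluster 11 the infected value was 1555 CPM (1401 to 1721), again with 0 UMIs in control cells, and in cluster 10 the values were 412 CPM (355 to 475) and 5.54 CPM (1.51 to 14.2). In mixed cluster 13 the infected cells had 6 UMIs where 5.47 were expected from free RNA. Infected cells of mixed clusters 14 and 8 stood at 103 CPM (47.0 to 195) and 22.2 CPM (14.3 to 33.1), from 9 and 24 UMIs where 3.59 and 9.78 were expected. Infected cluster 0 stood at 18.0 CPM, where 67.6 of its 111 UMIs were expected from free RNA. With each cell thinned to 500 UMIs, 13.4% of the infected cells (12.6 to 14.2%) and 0.0508% of the control cells had a UMI of Isoform0027597. Without thinning the shares were 19.7% and 0.525%, and 3.08% of infected empty droplets were expected to hold a UMI.

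Isoform0011647 had 736 UMIs in the infected cells (39.1 CPM) and 0 in the control cells. Against a bound of 3 UMIs it was 214-fold higher in the infected library, and 173-fold at the low end of the exact interval. It was spread over many clusters, with 43.1% of its UMIs in cluster 0 at 51.3 CPM (45.8 to 57.2) and a level of 92.6 CPM (71.5 to 118) in cluster 16. In mixed cluster 13 it stood at 57.6 CPM (40.8 to 79.1) in infected cells and at 0 UMIs in control cells, which allows up to 3.61 CPM. Infected cluster 7 had only 1.91 CPM (0.394 to 5.58). With each cell thinned to 500 UMIs, 2.00% of the infected cells (1.68 to 2.36%) had a UMI, and 9.48% without thinning, against 0 of 5909 control cells in each case, which allows up to 0.0508%. In infected empty droplets 0.120% were expected to hold a UMI of it.

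Isoform0011498 was the lowest in the infected library by the same rule. It had 3256 UMIs in the control cells (198.5 CPM) and 0 in the infected cells. Against the bound of 3 UMIs it was 1247-fold lower in the infected library, and 1014-fold at the low end of the exact interval. Control cluster 5 held 84.7% of the UMIs, at 1045 CPM (1006 to 1085), and control cluster 22 stood at 826 CPM (662 to 1019). In mixed cluster 12 it reached 233 CPM (183 to 293) in control cells and 0 UMIs in infected cells, which allows up to 5.82 CPM. In control cluster 1 it had 16 UMIs, where 7.52 were expected from free RNA. Thinned to 500 UMIs, 6.84% of the control cells (6.21 to 7.51%) had a UMI, and 15.3% without thinning, against 0 of 6949 infected cells. In control empty droplets 0.501% were expected to hold a UMI of it.

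Isoform0002345 had 6200 UMIs in the control cells (378 CPM) and 3 in the infected cells (0.159 CPM), a 2375-fold difference (812 to 11518). All 3 infected UMIs came from 1 cell, so the size of the fold rests on that cell. Control cluster 1 held 75.4% of the UMIs, at 1030 CPM. In mixed cluster 13 the control value was 752 CPM (694 to 813) and infected cells had 0 UMIs, which allows up to 4.55 CPM. In mixed cluster 4 the control value was 236 CPM (202 to 274), also against 0 UMIs in infected cells. Thinned to 500 UMIs, 768 of 5909 control cells (12.2 to 13.9%) and 1 of 6949 infected cells had a UMI, and without thinning the shares were 29.5% and 0.0144%. In control empty droplets 0.722% were expected to hold a UMI of it. In control cluster 5 it stood at 6.44 CPM (3.75 to 10.3).

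**Figure D4:**
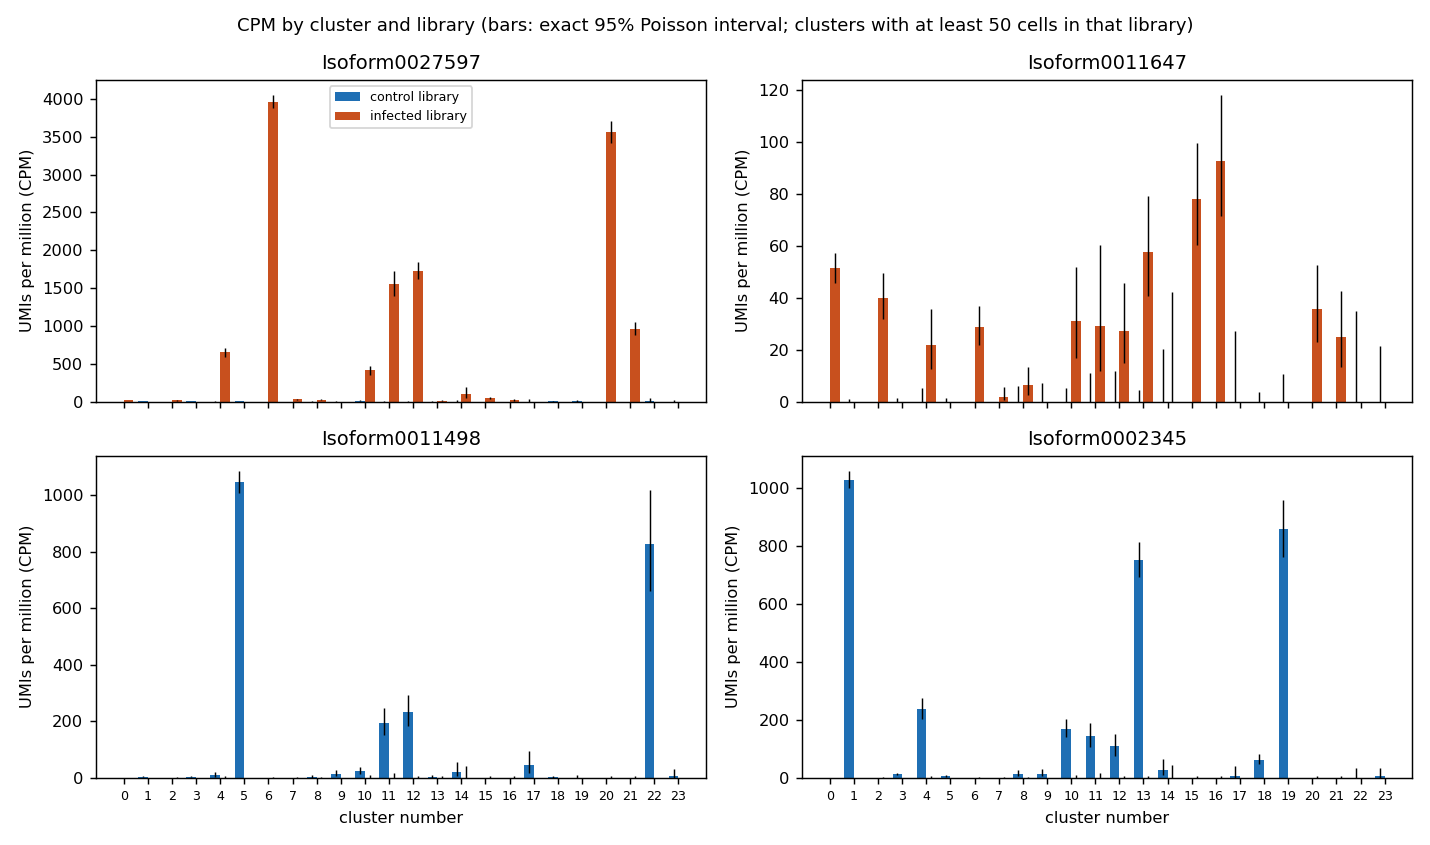
CPM of the 4 named features by cluster, with 1 panel per feature, control and infected bars side by side and error bars giving the exact 95% Poisson interval, for clusters with at least 50 cells in that library. Isoform0027597 peaks in infected clusters 6 and 20, Isoform0011647 is spread over infected clusters, Isoform0011498 peaks in control clusters 5 and 22, and Isoform0002345 peaks in control clusters 1, 13 and 19.

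The third comparison asked how far features differed inside the same cluster. The control and infected cells of clusters 4, 10, 11 and 12 were each other's closest match by profile. Those of clusters 13 and 14 were not, nor were those of cluster 8, where the control cells matched infected cluster 6 better (rho 0.684 against 0.654). The profiles differed in depth, for which rho was not adjusted. In all 7 mixed clusters compared, at least 11.3% of the features with enough UMIs differed 2-fold or more. The share was 32.7% in cluster 8 (591 higher and 428 lower of 3116 features) and 31.9% in cluster 4 (365 higher and 548 lower of 2864). It was 21.3% in cluster 11, 21.1% in cluster 14 and 20.8% in cluster 13. Clusters 10 and 12 had 14.7% and 11.3%. Between control cluster 1 and infected cluster 0, the closest pair of single-library clusters, 733 features were higher and 1290 lower in infected cluster 0, 21.1% of 9604. For that pair the counts were 1069 and 2038 at a minimum of 20 UMIs, 332 and 439 at 200 UMIs, and 386 and 458 at 4-fold. The median count over the 7 mixed clusters was 108 higher and 116 lower, and deeper clusters had more features above the minimum of 50 UMIs. With every cluster and library thinned to 87513 UMIs the share was 26.9% for the closest pair, 44.9% in cluster 8, 36.4% in cluster 4, 27.0% in cluster 13 and 12.0% in cluster 12. Inside these mixed clusters 15.5% of the neighbours of control cells were infected cells and 11.5% of those of infected cells were control cells. With 20 cells of each library drawn from a cluster, the share of neighbours from the other library ran from 13.6% in cluster 8 to 45.2% in cluster 10, against 51.3% under random mixing. The median counts were 343 higher and 326 lower at a minimum of 20 UMIs, 27 and 21 at a minimum of 200 UMIs, and 52 and 53 at 4-fold.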

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

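The patterns below were chosen after the clusters were seen, while the bounds of each test were set before its value was computed. Every explanation is a hypothesis found and tested on the same libraries, and infection, fish and library handling coincide in this design and cannot be told apart.

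Most cells lay in clusters of a single library beside mixed clusters. A difference in UMIs per cell is argued against, because with every cell thinned to 500 UMIs the share in single-library clusters was 65.5% of control and 79.0% of infected cells, at least 1.06 times its unthinned value. Of the features past the size rule between control cluster 1 and infected cluster 0, the closest pair, 98.3% still passed after subtraction of free RNA. The estimated level was 1.43% and 1.58% of the median control and infected cell, so few features could have failed. Free RNA is therefore argued against only at that level and for these features. Clustering after subtraction was not run, so its part in the separation was not tested. Features of the closest pair kept a median of 0.273 of their log2 ratio in the mixed clusters, from -0.0929 in cluster 14 to 0.773 in cluster 13. The fraction was under 0.5 in 5 of 7 clusters where at least 6 were asked for. The features were picked for their ratio in the pair, and the mixed clusters for holding cells of both libraries. Both choices can lower the fraction, so a shift common to all cells of a library stays open. Such a shift may account for part of the separation, and a response to infection that differs between cell types is also open and was not tested.

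Clusters 9, 17 and 22 were nearly absent from the infected library. With barcodes of 200 to under 500 UMIs added, the log2 ratio of shares was -3.59 (-3.87 to -3.33). Among such barcodes that differed from the empty profile, 29.1% in the control and 5.03% in the infected library matched these clusters. The profiles used for these clusters came mostly from control cells, so infected barcodes could be placed elsewhere. Barcodes under 200 UMIs were not examined. Cells below the UMI minimum are therefore argued against only for that range and that assignment. Assignment of every cell by control cluster profiles found 168 infected and 771 control cells, against 42 and 756 as clustered. The log2 ratio was then -2.43 (-2.68 to -2.19). Infected cells whose profile was shifted from the control profiles could still be assigned to other clusters. Placement of their infected cells in other clusters is therefore argued against only for that assignment. Both explanations together were not tested. Loss of these cells in preparing the suspension, a difference between fish and an effect of infection may each explain it and were not tested.

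Some features differed in the same direction in most mixed clusters, 41 higher and 40 lower in at least 4 of the 7. After subtraction of free RNA 92.6% of them still did so. Free RNA is argued against only at its estimated level, which was low enough that few features could have failed. Summed over all pairs of the 7 clusters, with a feature counted in each pair that shares it, the overlaps came to 667 higher and 559 lower, against 189.8 and 150.7 under independence, but all clusters come from the same libraries, so an effect of library, fish or infection may raise these overlaps alike. No biological explanation was tested.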

How the results depend on the processing

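No paired analysis was possible because each group has 1 library and no result comes from a test. Clustering of thinned cells, clustering without the features past the size rule, each library's automatic doublet threshold and barcodes tested from 200 UMIs were chosen after seeing the data. All 44 alternative log2 ratios of the 4 named features lay inside the main intervals. The UMI minimum and the size of the fold do not enter these ratios, so those settings could not move them. The intervals of Isoform0011647 and Isoform0011498 have no limit on the side of larger differences, so a larger difference could not leave them. Of 56 alternative feature counts 38 stayed within 1.5 times, 4 rose and 14 fell further. Of 52 log2 ratios of cluster shares 44 stayed inside the main interval, 6 rose, 1 fell and 1, whose main interval excludes 0, changed sign. In all 50 kept their sign, and the other change of sign was cluster 13, at 0.0016 without the features past the size rule. Unthinned, 5 of 8 shares of cells with a UMI rose and 3 stayed inside the interval. Causes of the shifts below were not tested, except that a higher minimum or a larger fold leaves fewer features to pass. Leaving out features that differed between these libraries also by itself favours lower shares in single-library clusters.

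The percent of control and of infected cells in single-library clusters (61.5% and 73.4%) was 63.5% for control cells at Leiden resolution 0.5, where the infected share stayed inside its interval, 64.6% and 74.9% at resolution 2.0, 66.7% and 76.8% with features scaled within each library, 33.8% and 61.1% without the features past the size rule, and 65.5% and 79.0% with thinned cells. It was 84.2% and 86.6% with cells by the order-of-magnitude threshold alone, 81.3% and 87.3% for barcodes of at least 1000 UMIs, 63.8% and 77.2% with doublets kept, 64.4% and 76.7% with automatic doublet thresholds, and 65.0% and 43.2% with barcodes tested from 200 UMIs.

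The log2 share ratio of cluster 10 was -0.26 with features scaled within each library, -0.14 without the features past the size rule, -0.031 by the order-of-magnitude threshold, -0.12 at 1000 UMIs and 0.10, a change of sign, from 200 UMIs. That of cluster 11 was -0.23 by the order-of-magnitude threshold. That of clusters 9, 17 and 22 was -3.95 with features scaled within each library and -5.07 from 200 UMIs. Cluster 12 stayed between 0.52 and 0.82. Some settings had no cluster that corresponded to cluster 14 or to each of clusters 9, 17 and 22 and gave no value for them.

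Over all cells 503 features were higher and 696 lower at a minimum of 200 UMIs, and 319 and 434 at 4-fold. The median over compared clusters was 343 and 326 at a minimum of 20 UMIs, 27 and 21 at 200 UMIs and 52 and 53 at 4-fold. Against 108 higher and 116 lower over 7 clusters, the medians were 124.5 and 64 over 4 clusters by the order-of-magnitude threshold, 134.5 and 69.5 over 4 at 1000 UMIs, and 164 and 113 over 11 from 200 UMIs. Haemoglobin features could not be named, so the 20 most abundant features were left out in their place. The mitochondrial filter and the alternatives for gene lists were not run, since features carry no names. Depth limits how many features can be tested, from 394 in cluster 14 to 15752 over all cells.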

Other observations

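Values in this part were chosen after the data were seen.

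Counts of features past the size rule were set side by side over the mixed clusters. Of 1135 features higher in the infected library in at least 1 of the 7 mixed clusters, 856 passed the size rule in 1 cluster only and 279 in 2 or more. Of 1241 lower features, 1053 passed in 1 cluster only and 188 in 2 or more. Clusters differ in depth, with 394 to 3116 features tested, so a feature that passed in 1 cluster can have differed below the UMI minimum in others, and no difference between clusters was tested. Features of the closest pair lay in the same direction in 44.9% of cases in cluster 14 and in 64.9 to 91.7% of cases in the other clusters. In all 7 clusters 1 feature was higher and 0 were lower, and after subtraction of free RNA 0 were higher in all 7.

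A small set of features was near absent from 1 library. At least 100 UMIs in the infected cells and at most 3 in the control cells were found for 33 features, and the reverse for 22. These features held 0.0435% of the infected and 0.105% of the control UMIs. The cluster with most UMIs of a feature held a median of 52.8% of them in the infected set and 72.0% in the control set. In the library that held them, 11 of the 33 and 10 of the 22 had at least 20 UMIs in a mixed cluster at over 5 times the level expected from free RNA.

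Cells of the small clusters 24, 25, 28, 29 and 30 had 38.1%, 48.4%, 45.9%, 42.9% and 48.0% of their neighbours in the other library, with 66, 45, 26, 25 and 18 cells. Cluster size moves this measure, so 20 cells of each library were also drawn 100 times from each mixed cluster with enough cells, and 10 neighbours were taken among the cells drawn. Clusters 24 and 25 then had 43.8% and 46.5% of neighbours in the other library, clusters 10 and 12 had 45.2% and 44.1%, and clusters 8, 14 and 19 had 13.6%, 21.5% and 12.6%, against 51.3% under random mixing.

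Barcodes outside the cells also carried signal. Of 2543 control barcodes with 200 to under 500 UMIs, 2406 differed from the empty profile, and so did 1651 of 1737 infected barcodes. They held 2.90% and 1.81% of all UMIs. In the control library 148 features had at least 8-fold higher CPM in empty droplets than in cells, and in the infected library 98, with 40 features in both sets. They made up 2.29% of the UMIs of control empty droplets against 0.144% of those of control cells, and 1.06% against 0.0683% in the infected library.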
